A study of Homo sapiens with 16 samples.

How the data were processed

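The series measured RNA in HEK293T cells, a human embryonic kidney line, that carried either a control shRNA or an shRNA against RNASET2, a secreted and lysosomal ribonuclease of the T2 family. Cells of each line received 1 mM palmitate on 0.5 mM bovine serum albumin (BSA), or 0.5 mM BSA as vehicle, for 8 h. The series description calls the control cells wildtype where the sample titles give a control shRNA; the titles were followed here, and if the description is right every knockdown comparison also holds the effect of carrying an shRNA. Each of the 4 groups had 4 libraries, and the labels placed replicates 1 and 2 in batch 1 and replicates 3 and 4 in batch 2. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

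Per the labels' protocols, total RNA was treated with DNase I, depleted of ribosomal RNA and separated into short and long fractions. The long fraction was fragmented, and the pooled RNA was treated with T4 polynucleotide kinase and made into libraries with a thermostable group II intron reverse transcriptase (TGIRT-seq). This enzyme reads through structured RNA, so tRNA and other small RNAs are counted beside mRNA. Per the submitters' processing notes, cutadapt 2.8, HISAT2 2.1.0, SAMtools 1.10, bedtools 2.29.2, DESeq2 and the GRCh38 build were used; their roles and the handling of strand and of reads with several matches are not given in the sources used here. The deposited values are raw counts per annotated feature, as whole numbers, in 16 files of 4 columns holding an identifier, a symbol, an RNA class and the count.

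Overlapping genes, antisense partners, pseudogenes and small RNAs with near-identical copies are uncertain for that reason. A feature that a library did not list was given a count of 0. The 89 ERCC spike features and 1 further spike feature, with 29 to 97 counts per library, were left out. Library totals ran from 18787703 to 29993694 counts, and protein-coding genes took 18.2% to 44.7% of a library. Cytosolic tRNA took 22.2% to 60.9% of the counts of a library, so depth over mRNA varied more than the totals did. No pair of libraries was a duplicate: the smallest of 120 chi-square ratios per degree of freedom was 7.44.

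Of 49392 features, edgeR's filterByExpr with its minimum count of 10 kept 23822. Libraries were scaled by TMM on these features, and normalised counts are counts per 1e6 counts (CPM) of the scaled library size. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) over all 16 libraries with a term for each group and for batch, and Benjamini-Hochberg adjustment at 0.05. A standard error (SE) is the log2 fold change divided by the root of the F statistic. The contrasts were palmitate against BSA in each line, knockdown against control under each treatment, and their interaction. The means of the palmitate effects over both lines and of the knockdown effects over both treatments were added after the data were examined; the other contrasts, the rule for named genes, 29 gene lists and the main alternatives were fixed before the data were examined.

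The text names RNASET2 and, for each contrast, protein-coding genes past the threshold with a mean of at least 5 CPM and the same direction in both batches, up to the 8 largest changes each way. Up to 2 features each way that are not protein-coding, up to 4 members of a discussed list by smallest p, and 5 each way for the interaction followed the same criteria. Genes named outside this rule are said to be so, and 2 genes that met it are not reported here. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation; 27 lists had at least 3 tested members. Members were also adjusted over the list alone. Shares of 21 RNA classes were compared with exact permutation tests, two-sided, 4 libraries against 4, and exact sign-flip tests over same-numbered pairs.

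Same-numbered libraries of different groups were checked for pairing before calls were compared. Over 9687 genes, deviations from the group means correlated at 0.26 to 0.78 in 24 of 24 same-numbered pairs (median 0.58), against a median of 0.35 for other numbers of the same batch. Within a batch 9 of 12 correlations exceeded 0.1 (range -0.06 to 0.72), and 8 of 16 libraries correlated best with their own number in every other group. The pairing comes from these values, not from a label, and a fit with the replicate number as a block was run beside each test. Control BSA replicates 1 and 2 may pair crosswise. By chi-square ratio replicate 1 was nearer to other groups' replicate 2 (27.5, 27.8, 32.8) than to their replicate 1 (38.8, 80.2, 77.7). Replicate 2 was nearer to their replicate 1 (11.1, 17.2, 38.8) than to their replicate 2 (24.7, 49.2, 43.4). The groups are knockdown BSA, control palmitate and knockdown palmitate in turn. Results that use the pairing are limited by this. The first principal component held 42.5% of the variance and followed batch (r squared 0.94).

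Alternatives were DESeq2 1.42.0, its size factors in edgeR (RLE), TMM on protein-coding genes, protein-coding genes alone, no filter on low counts, a mean of at least 5 CPM, no batch term, each batch alone, the groups compared alone, the replicate block, and each library left out in turn. The replicate block with a GC correction was chosen after seeing the data: each library's loess trend (span 0.5) on transcript GC content, from GENCODE 29 and present for 99.0% of tested features, was removed through offsets. Coordinates are those of GENCODE 29 on GRCh38.

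The pipeline was tested on simulated counts for palmitate in control shRNA, drawn from the means and library sizes of the 23822 genes with 200 genes changed. It recovered 60 of 67 genes changed 1.5-fold, 66 of 67 changed 2-fold and 66 of 66 changed 4-fold, and called 5 unchanged genes. With the replicate block, 59 of 67, 65 of 67 and 66 of 66 were recovered, with 9 unchanged genes called. The changed genes all had a mean of at least 5 CPM, and the simulated libraries lack the deviations that same-numbered libraries share. Recovery of lower genes was not tested, and recovery in the real libraries may be less. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.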

Results

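Libraries of control shRNA and RNASET2 knockdown HEK293T cells, treated for 8 h with 1 mM palmitate or with BSA vehicle, were compared in a 2 by 2 design with 4 libraries in each of 4 groups. Depth ran from 18787703 to 29993694 counts per library. The title of the series names RNASET2 and mRNAs that protect against lipotoxicity, the damage that excess fatty acid does to cells, so the comparisons ask which RNAs changed with palmitate, which differed with knockdown, and whether knockdown altered the palmitate response.

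RNASET2 itself (ENSG00000026297, chromosome 6, 166929504 to 166957191, minus strand) was only slightly lower in the knockdown libraries. Under BSA it measured 9.44 ± 0.83 CPM in control cells and 7.75 ± 0.52 in knockdown cells (SD, n = 4 each), 17.9% lower (exact permutation test, two-sided, p = 0.0286; 0.0571 adjusted over 4 tests). Under palmitate it measured 9.32 ± 0.86 and 7.14 ± 1.39 CPM, 23.4% lower (exact permutation p = 0.0571). In the edgeR test over all genes the log2 fold change was -0.29 ± 0.10 (SE, adjusted p = 0.606) under BSA and -0.39 ± 0.10 (adjusted p = 0.755) under palmitate. Averaged over both treatments it was -0.34 ± 0.07 (adjusted p = 0.0648, and 0.0404 with the replicate block). Batches 1 and 2 fitted alone, with 2 libraries per group, gave -0.28 and -0.26 under BSA but -0.66 and -0.16 under palmitate, and -0.47 and -0.21 on average. AL159163.1 (ENSG00000249141), which overlaps RNASET2, was 19.4% lower under BSA (exact permutation p = 0.0286) and 13.9% lower under palmitate (exact permutation p = 0.229), and reads from the shared stretch cannot be assigned to either gene here.

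**Figure D1:**
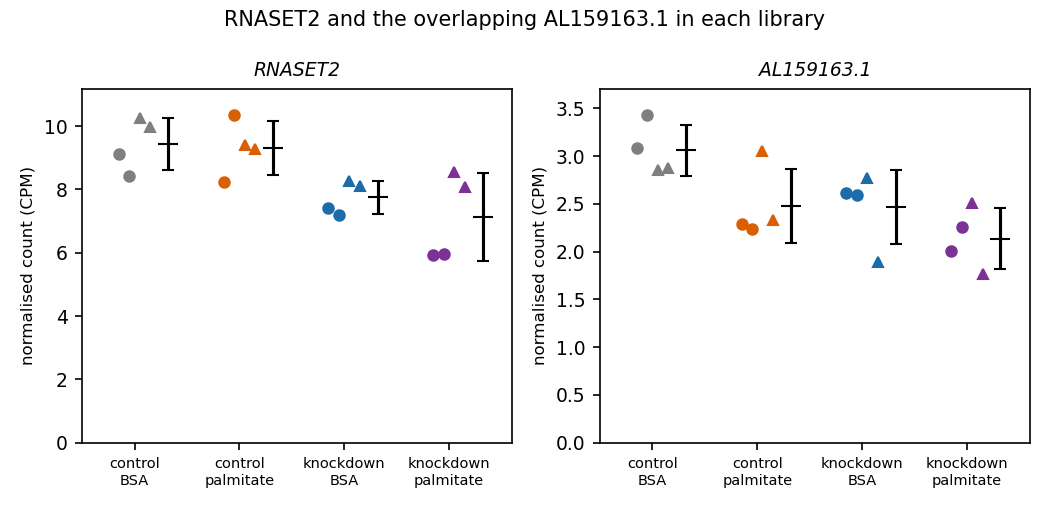
Normalised counts (CPM, vertical axis from 0) of RNASET2 and of the overlapping AL159163.1 in each of the 16 libraries; circles are batch 1, triangles are batch 2, and bars are the mean and SD of 4 libraries. RNASET2 ran from 8.44 to 10.2 CPM in control cells under BSA and from 7.19 to 8.27 in knockdown cells under BSA.

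In control shRNA cells HMOX1 and SLC7A11 had the largest rises with palmitate among called protein-coding genes of at least 5 CPM. HMOX1, which encodes heme oxygenase, rose from 8.61 ± 1.98 to 21.9 ± 5.04 CPM (SD, n = 4; log2 fold change 1.36 ± 0.23, SE), and SLC7A11, the cystine transporter, rose from 22.4 ± 4.37 to 46.0 ± 9.63 CPM (1.06 ± 0.17). GARS, the glycyl-tRNA synthetase, rose by 0.50 ± 0.08 and CKAP2, a spindle protein, by 0.38 ± 0.06. LPCAT1, an acyltransferase that makes phosphatidylcholine, had a log2 fold change of -0.64 ± 0.10, from 46.8 ± 3.73 to 29.9 ± 5.46 CPM, and ACAP3 (-0.53), HES6 (-0.45), PAQR4 (-0.44), SLC25A1 (-0.42), AIF1L (-0.39) and NME3 (-0.37) were lower too. SLC25A1 is the mitochondrial citrate carrier. Among features that are not protein-coding, the pseudogene EIF2S2P4 rose by 0.63, and below the expression limit ASNSP1 (0.96) and a MALAT1 fragment (0.97) completed the set; a pseudogene's reads cannot be told from those of its parent gene here.

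These were 14 features in all, 7 higher and 7 lower of 23822 tested, each with an adjusted p between 0.0368 and 0.0383 by edgeR's quasi-likelihood test. The replicate block raised the count to 222 (96 higher, 126 lower), and with TMM on protein-coding genes the split was 7 higher and 4 lower. RLE size factors, no batch term and the groups compared alone each gave 0. Leaving out replicate 1, 2, 3 or 4 of the BSA group gave 0, 0, 1 or 4 calls, and leaving out replicate 1, 2, 3 or 4 of the palmitate group gave 0, 41, 0 or 0. Batch 1 alone gave 0 and batch 2 alone 2. In the blocked fit with a GC correction HMOX1, SLC7A11, GARS, LPCAT1 and AIF1L stayed past the threshold, while CKAP2, ACAP3, HES6, PAQR4, SLC25A1, NME3 and EIF2S2P4 did not.

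In RNASET2 knockdown cells no gene passed the main test with palmitate, and the genes given here were called with the replicate block. HMOX1 had a log2 fold change of 1.32 ± 0.24 (SE, n = 4 each; 6.27 ± 1.65 to 15.5 ± 5.65 CPM, SD), SLC7A11 0.92 ± 0.16, CTH, a cysteine-synthesis enzyme, 0.92 ± 0.15, and STC2, a secreted stress protein, 0.66 ± 0.10. LPCAT1 stood at -0.52 ± 0.10. The count was 0 by edgeR (1265 at an unadjusted p under 0.05), 24 by DESeq2, and 15 with the replicate block (12 higher, 3 lower), among them HMOX1, SLC7A11, CTH, STC2, ATF3, GARS and LPCAT1. Without palmitate replicate 2 the count was 14 and without BSA replicate 2 it was 2; batch 1 alone gave 0 and batch 2 alone 3.

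Averaged over both lines, palmitate changed 281 features, 131 higher and 150 lower (edgeR, adjusted p under 0.05). HMOX1 (log2 fold change 1.34 ± 0.17, SE, 8 libraries against 8, adjusted p = 0.00116), the stress transcription factor ATF3 (1.18 ± 0.17, adjusted p = 0.00328) and SLC7A11 (0.99 ± 0.12, adjusted p = 0.00116) were followed by HERPUD1 (0.87), CTH (0.84), HFM1 (0.74), the neutral amino acid transporter SLC1A4 (0.72) and XBP1 (0.71). SNN (-0.61), LPCAT1 (-0.58), NOTCH3 (-0.55), MAP2K6 (-0.53), SRGAP3 (-0.49), BTN3A2 (-0.47), C14orf132 (-0.46) and SCN9A (-0.46) were the most reduced. These are protein-coding genes of at least 5 CPM with the same direction in both batches, and larger changes were called below that limit. MIR3178 (2.58 ± 0.31) and MIR7704 (1.88 ± 0.29) rose, with wide spread between libraries (MIR7704 36.5 ± 29.8 CPM, SD, in knockdown cells with palmitate), and AL133325.3 (-0.40) and MCM3AP-AS1 (-0.25) fell. CPT1A, which carries long-chain fatty acids into mitochondrial oxidation, rose by 0.65 ± 0.09 (adjusted p = 0.00328). It was the only 1 of 16 genes of fatty acid oxidation called over all genes (2 rose and 1 fell adjusted over the list alone); 11 of 16 were higher, with a median of 0.03 (camera adjusted p = 0.052; adjusted p = 0.36 with an estimated correlation).

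The block raised this count to 750 (337 higher, 413 lower), and with TMM on protein-coding genes the split was 171 higher and 117 lower; no batch term gave 85. Calls fell to 145 without control BSA replicate 3, to 159, 152 and 159 without control palmitate replicates 1, 3 and 4, to 174, 128, 100 and 168 without knockdown BSA replicates 1 to 4, and to 146, 187, 148 and 160 without knockdown palmitate replicates 1 to 4. Batch 1 alone gave 0 and batch 2 alone 28.

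Genes of the integrated stress response, targets of ATF4, were higher with palmitate in 26 of 26 cases in both lines. In control cells the list's median log2 change was 0.41, and 20 of 26 members rose when adjusted over the list alone (1 over all genes); in knockdown cells the median was 0.39, with 20 adjusted over the list alone and 0 over all genes. SLC7A11, CHAC1, a glutathione-degrading enzyme (1.61 ± 0.29 in control and 1.37 ± 0.28 in knockdown cells, SE), CTH (0.76 and 0.92) and STC2 (0.50 and 0.66) had the smallest p-values in control cells. Camera gave an adjusted p = 1.01e-32 in control cells and 2.02e-46 in knockdown cells. With an estimated correlation these were adjusted p = 0.0363 and 0.0088, and with the block as well adjusted p = 0.0916 and 0.0336.

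**Figure D2:**
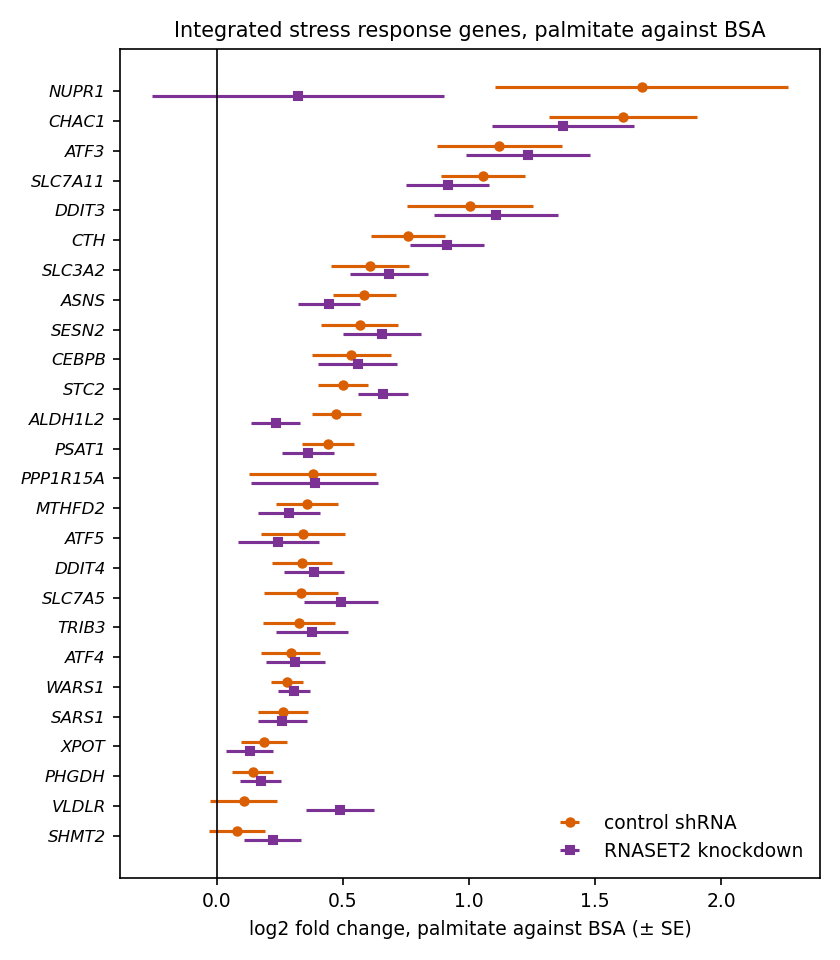
Log2 fold change with palmitate against BSA (horizontal axis, bars are SE) of the 26 integrated stress response genes in control shRNA (circles) and RNASET2 knockdown (squares) cells, 4 libraries per group. All 26 lie above 0 in both lines, with medians of 0.41 and 0.39.

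Chaperones and degradation factors of the endoplasmic reticulum, targets of XBP1 and ATF6, were higher in 21 of 22 cases in each line. In control cells 15 rose when adjusted over the list alone and 0 over all genes, and in knockdown cells 13 and 0; averaged over both lines 17 rose and 1 fell adjusted over the list alone, and 11 rose over all genes. HERPUD1 (0.99 ± 0.18 and 0.75 ± 0.18, SE), DNAJB9 (1.15 and 0.79) and the chaperone HSPA5 (0.66 and 0.52) are examples. Camera's adjusted p was 7.06e-23 and 2.78e-18 in the lines, and with an estimated correlation adjusted p = 0.0893 and 0.112, with 0.044 for the average of both lines.

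Mitochondrially encoded mRNAs were higher in 13 of 13 cases in each line, 4 in control and 8 in knockdown cells adjusted over the list alone, with none over all genes in either. Averaged over both lines 3 of 13 rose over all genes, and 7 with the replicate block. MT-ND2 (0.43 ± 0.10 and 0.43 ± 0.10, SE) and MT-ND1 (0.46 and 0.38) are subunits of complex I. With an estimated correlation the list had adjusted p = 0.216 and 0.112 (camera). As a share of all counts, mitochondrial mRNA was 1.053-fold with palmitate over the 8 same-numbered pairs and higher in 3 of 8 (exact sign-flip p = 0.516).

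Cholesterol synthesis and uptake genes were lower in most cases: 4 of 19 were higher in control cells and 2 of 19 in knockdown cells. Adjusted over the list alone, 6 fell in control cells and 1 in knockdown cells, and none did over all genes; averaged over both lines 9 fell and 1 rose adjusted over the list alone, and 2 fell over all genes, among them LSS (-0.33 ± 0.05, SE), the lanosterol synthase. Fatty acid synthesis and desaturation genes were higher in 2 of 15 cases in each line, and on average 8 fell and 2 rose adjusted over the list alone, and 1 fell over all genes, the elongase ELOVL6 (-0.24 ± 0.05). With an estimated correlation the adjusted p of the average was 0.253 for the first list and 0.22 for the second.

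Smaller shifts were seen in other lists, averaged over both lines. Cytosolic heat shock proteins were higher in 15 of 15 cases (7 adjusted over the list alone, 1 over all genes, STIP1, 0.22 ± 0.05, SE). Replication-dependent histones were higher in 25 of 26 cases (8 adjusted over the list alone, 1 over all genes, H2BC17, 0.40 ± 0.07). NRF2 targets were higher in 11 of 18 cases (12 in control and 9 in knockdown cells) with a median of 0.03, with 6 higher and 1 lower adjusted over the list alone and 3 higher over all genes (HMOX1, SLC7A11 and the ferritin gene FTH1, 0.41 ± 0.09). Of the immediate early genes 9 of 13 were higher (4 rose and 1 fell adjusted over the list alone), and FOSB (1.22 ± 0.22) and FOS (1.44 ± 0.30) rose and MYC fell by 0.27 over all genes. Camera's adjusted p with an estimated correlation was 0.237, 0.253, 0.264 and 0.387 for these 4 lists. Of 27 lists, 10 passed on average at the preset correlation and 2 with an estimated one.

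The palmitate responses of both lines were set side by side to ask whether knockdown altered them. The interaction called 0 genes by edgeR (567 at an unadjusted p under 0.05), 0 by DESeq2 and 0 with the replicate block. This does not show that the responses were equal. RNASET2 RNA was only 17.9% lower under BSA and 23.4% under palmitate, and recovery of interactions was not simulated. An interaction also has a larger SE, for RNASET2 0.14 against 0.10 for palmitate in each line. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.18 (Spearman's rho 0.22) over 23822 features and at r = 0.52 (rho 0.48) over 11542 features of at least 5 CPM. The jackknife SE of the first value was 0.41, and simulated unchanged groups gave -0.02 to 0.03, though simulated libraries lack the deviations that same-numbered libraries share and so are no firm reference. Without control BSA replicate 1 the first value was r = -0.09, and in batch 2 alone r = -0.32 (batch 1 alone 0.25). The 281 features called on average had the same sign in both lines, with r = 0.96, and were chosen on the mean of both responses. In control and knockdown cells ATF3 (1.12 and 1.23) and XBP1 (0.70 and 0.72) were closer than DNAJB9 (1.15 and 0.79), HERPUD1 (0.99 and 0.75) or CHAC1 (1.61 and 1.37), none of which the interaction called.

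**Figure D3:**
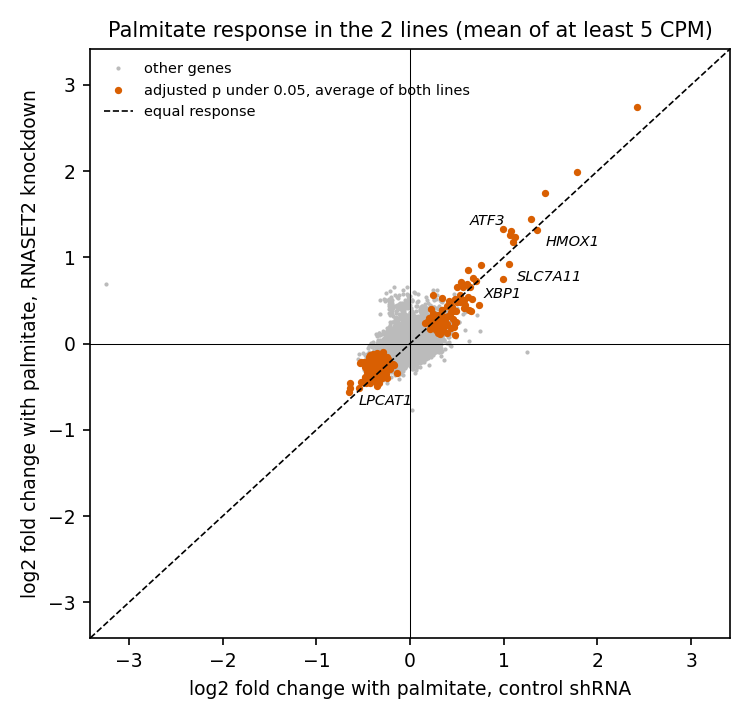
Log2 fold change with palmitate in RNASET2 knockdown cells (vertical axis) against control shRNA cells (horizontal axis) for features of at least 5 CPM; orange marks features with an adjusted p under 0.05 averaged over both lines, and the dashed line is an equal response. The orange features have the same sign in both lines, having been chosen on the mean of both.

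If palmitate raised the degradation of mRNAs by RNASET2, such mRNAs would be lower with palmitate in control cells. They would be higher with knockdown under palmitate if the knockdown relieved the degradation. RNASET2 RNA was only 23.4% lower there, and mRNAs degraded alike under BSA and palmitate need not fall with palmitate. With 7 genes called lower and 0 called higher (edgeR), none could be called both ways, so that count decides nothing. At an unadjusted edgeR p under 0.05, 65 genes met both, from 1478 lower and 293 higher. Independent lists of these sizes would share 18.2, and simulated unchanged groups that share the control palmitate libraries shared 129 on average (104 to 151). With these libraries split between the comparisons 12.5 genes were shared, against 19.9 for independent lists. The log2 changes correlated at r = -0.33 (simulated -0.50, split libraries 0.17), with a covariance of -0.0179 against a simulated -0.0379, a difference of 0.0200. The simulated libraries lack the deviations that same-numbered libraries share, so their values are no firm reference either. The split puts different control palmitate replicates in each comparison, so shared deviations enter both with the same sign. That alone can raise r and lower the overlap, so the split values decide nothing.

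Knockdown under BSA was accompanied by higher PFN2, a profilin that binds actin (44.6 ± 8.74 in control and 63.5 ± 3.55 CPM in knockdown cells, SD, n = 4 each; log2 fold change 0.53 ± 0.08, SE, edgeR adjusted p = 0.0196), and higher PRDX3, a mitochondrial peroxiredoxin (47.4 ± 4.19 and 66.2 ± 9.67 CPM; 0.48 ± 0.07, edgeR adjusted p = 0.0216). SYNGR2, a vesicle membrane protein (chromosome 17, 78168558 to 78173527), stood at -0.68 ± 0.07 (31.02 ± 0.71 and 19.3 ± 1.64 CPM, edgeR adjusted p = 0.00066), and CYB5R3, the cytochrome b5 reductase (chromosome 22, 42617840 to 42649568), at -0.63 ± 0.07 (23.8 ± 2.25 and 15.4 ± 1.84 CPM, edgeR adjusted p = 0.000583). LY6E (-0.62), the glycogenin GYG2 (-0.50), the proton pump subunit ATP6V0E1 (-0.44) and TBC1D13 (-0.42) were also lower. AL158835.3, an antisense RNA below the expression limit and named after its values were seen, had a log2 fold change of -4.72.

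These 9 features (2 higher, 7 lower; 20 with the replicate block, 3 higher and 17 lower) were 0 higher and 3 lower with RLE size factors and 3 higher and 5 lower with TMM on protein-coding genes. No batch term gave 3 and the groups compared alone 2. The count was 3, 3 or 4 without control replicate 2, 3 or 4 and 4, 3 or 3 without knockdown replicate 1, 3 or 4. Each batch alone gave 0.

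Under palmitate the knockdown cells had lower MRPL42, a mitochondrial ribosomal protein gene (54.9 ± 6.32 in control and 35.4 ± 4.07 CPM in knockdown cells, SD, n = 4 each; log2 fold change -0.63 ± 0.10, SE, edgeR adjusted p = 0.0277), GYG2 (-0.54 ± 0.09, edgeR adjusted p = 0.0464), SYNGR2 (-0.51 ± 0.07, edgeR adjusted p = 0.0224) and CYB5R3 (-0.47 ± 0.07, edgeR adjusted p = 0.0203). AL158835.3 made up the 5 called features, all lower (DESeq2 1 higher and 5 lower; RLE size factors 1, TMM on protein-coding genes 3, no batch term 0 and the groups compared alone 1). The count was 2, 1, 1 or 1 without control palmitate replicates 1 to 4 and 2, 1 or 1 without knockdown palmitate replicates 1, 2 or 3, and 0 in each batch alone.

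**Figure D4:**
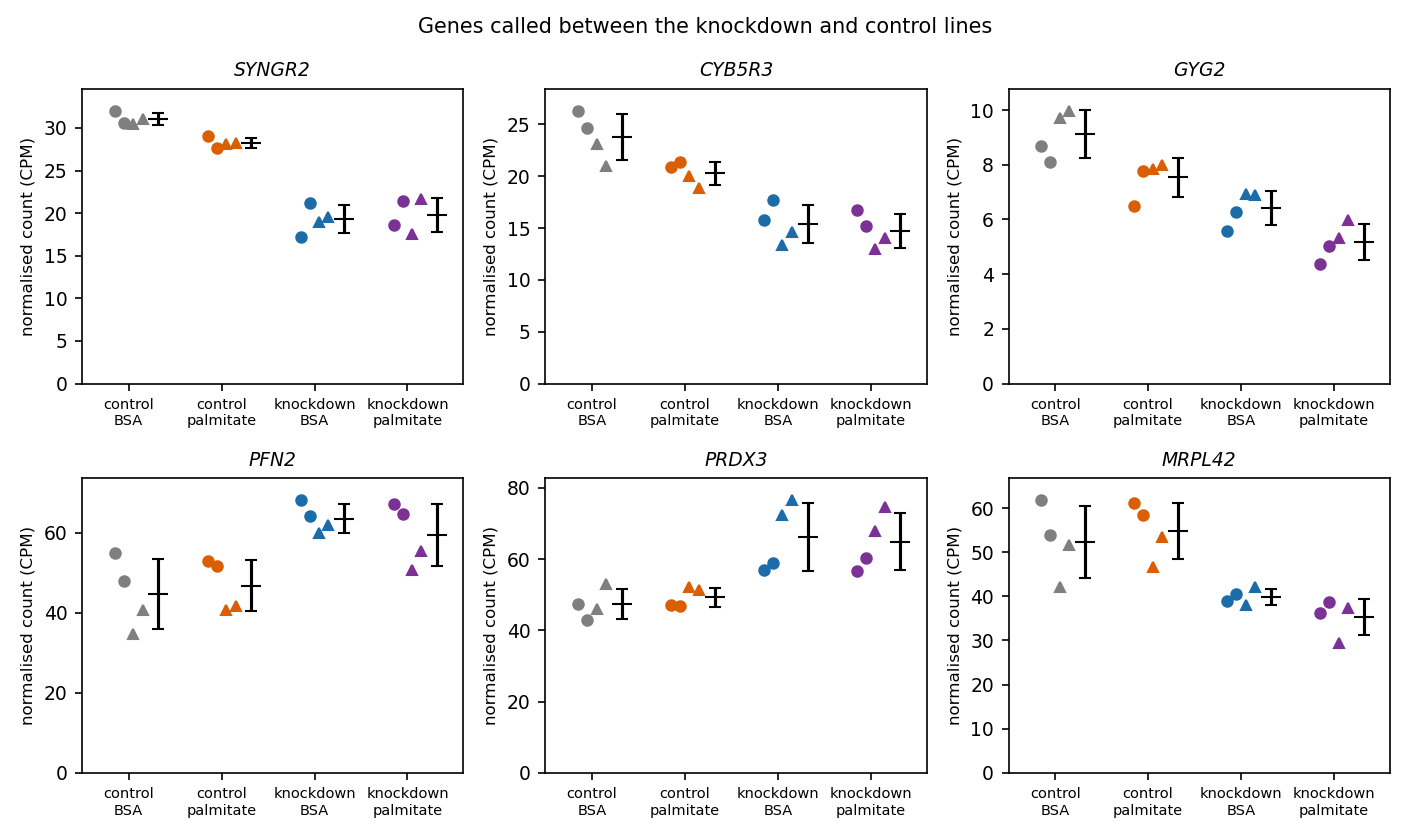
Normalised counts (CPM, vertical axes from 0) of SYNGR2, CYB5R3, GYG2, PFN2, PRDX3 and MRPL42 in each of the 16 libraries; circles are batch 1, triangles are batch 2, and bars are the mean and SD of 4 libraries. SYNGR2 averaged 31.02 and 28.3 CPM in control cells and 19.3 and 19.8 in knockdown cells.

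Averaged over both treatments, 36 features differed with knockdown, 6 higher and 30 lower (edgeR, adjusted p under 0.05). PFN2 (0.44 ± 0.06, SE), PRDX3 (0.44 ± 0.05), C3orf38 (0.38), FAM84B (0.28) and UCHL3 (0.22) were higher. The actin crosslinker FLNC (-0.68 ± 0.12), SYNGR2 (-0.60 ± 0.05), the small heat shock protein HSPB1 (-0.57), PTPRU (-0.56), CYB5R3 (-0.55), the growth factor MDK (-0.53), GYG2 (-0.52) and GNG4 (-0.51) were the most reduced protein-coding genes of at least 5 CPM. The knockdown log2 changes under BSA and under palmitate correlated across genes at r = 0.07 over all features and 0.31 over those of at least 5 CPM, and the 36 called features had the same sign under both treatments, having been chosen on their mean.

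The block raised this count to 105 (22 higher, 83 lower), and with TMM on protein-coding genes the split was 12 higher and 24 lower; no batch term gave 14. It was 20 without control BSA replicate 2, 23 and 22 without control palmitate replicates 3 and 4, 17 and 17 without knockdown BSA replicates 3 and 4, and 21 and 22 without knockdown palmitate replicates 3 and 4. Each batch alone gave 0.

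Among the lists, cytosolic ribosomal protein genes were higher with knockdown in 71 of 78 cases under BSA and 73 of 78 under palmitate, and nuclear genes of the respiratory chain in 27 of 30 under each, with none passing when adjusted over the list alone or over all genes. Camera gave adjusted p = 2.1e-14 and 9.53e-06 for the first and 1.03e-08 and 0.00011 for the second; with an estimated correlation they were adjusted p = 0.852 and 0.976 for both lists. Of the fatty acid synthesis genes, the elongase ELOVL1 was lower on average (-0.47 ± 0.06, SE, edgeR adjusted p = 0.0022), with FADS2 (-0.23), FADS1 (-0.18) and ELOVL6 (-0.15) past the threshold when adjusted over the list alone (4 in all, 1 over all genes). That list had adjusted p = 0.699 with an estimated correlation. The stress lists that moved with palmitate did not pass with knockdown: integrated stress response genes had a median of 0.01 on average (camera adjusted p = 0.319).

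Among RNA classes, the share of 18S and 28S rRNA that escaped depletion was 1.74% ± 0.62 in control cells under BSA and 3.71% ± 1.53 with palmitate (SD, n = 4 each; exact permutation test, two-sided, p = 0.0571), and 2.19% ± 0.62 and 5.14% ± 2.37 in knockdown cells (exact permutation p = 0.0857). None of the 21 classes passed in a comparison of 4 against 4, where the smallest possible p is 0.0286, so a single class could not have passed after adjustment. Over the 8 same-numbered pairs the rRNA share was 2.14-fold with palmitate and higher in 8 of 8. Its exact sign-flip p was 0.00781, the smallest the pairs can give (adjusted p = 0.0547). H/ACA snoRNA was 0.816-fold and snRNA 0.878-fold, lower in 8 of 8 pairs each with the same p. These are shares of a total that holds the rRNA. Without rRNA and mitochondrial features snRNA was higher in 1 of 4 pairs in each line, and H/ACA snoRNA in 0 of 4. In the edgeR fit, averaged over both lines, 162 of 253 snRNA features were higher (median log2 change 0.075, 0 called). The snRNA count also rests on the pairing: control palmitate replicate 1 (2.33%) exceeded control BSA replicate 2 (2.246%). The sign-flip test takes the 8 pairs as independent, though same-numbered libraries of all 4 groups share deviations, so these p-values may be too small. No class passed these share tests after adjustment over 21. As single features, 18S rRNA (log2 fold change 1.16) and 28S rRNA (1.37) were called higher with palmitate averaged over both lines. Both were called by edgeR at an adjusted p under 0.05, also with the replicate block. The 18S and 28S share was also higher in knockdown cells in 4 of 4 same-numbered pairs under each treatment, and no sign-flip test was run on these pairs.

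**Figure D5:**
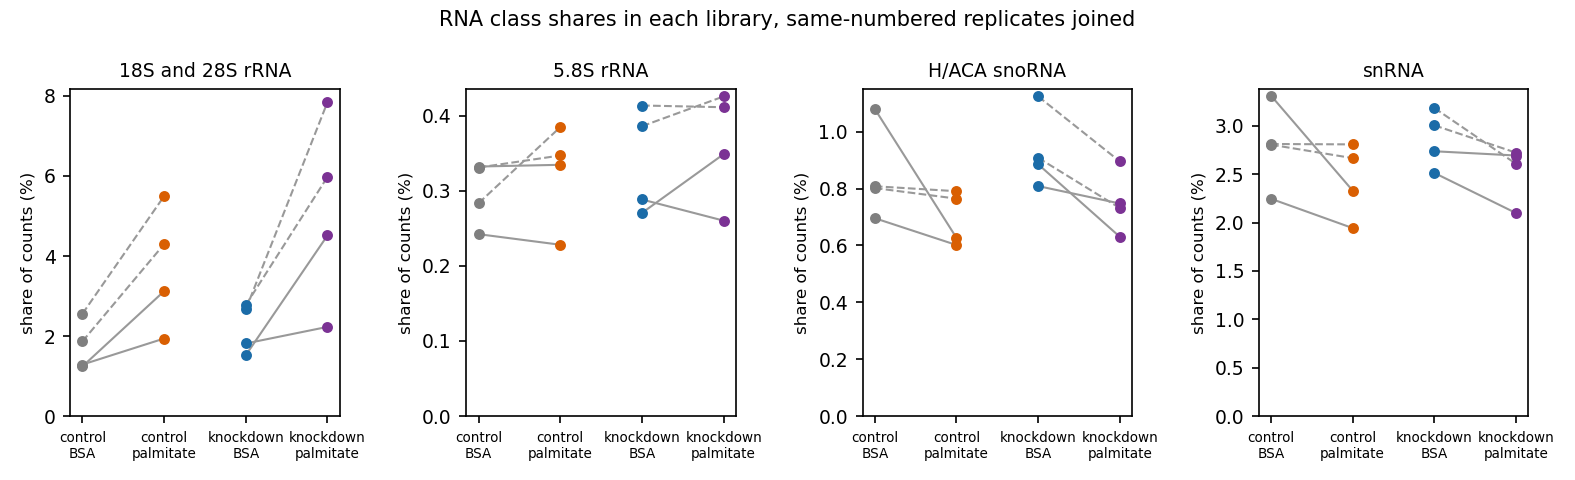
Share of all counts (percent, vertical axes from 0) taken by 18S and 28S rRNA, 5.8S rRNA, H/ACA snoRNA and snRNA in each of the 16 libraries; lines join same-numbered libraries of a line, solid for batch 1 and dashed for batch 2. The 18S and 28S share was higher with palmitate in 8 of 8 pairs.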

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

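The tests of technical explanations were chosen after the results they weigh had been seen, the gene list test was fixed before the data were examined, and the tests of the 5.8S rRNA share, of each called gene's neighbours taken singly, of line labels with a library left out and of splits that part every pair were written after a first look at what they measure.

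In 276 groups of 4 libraries examined, 18 had 1 library far from the other 3, against 13.8 that chance would give. With palmitate in control cells these were HMOX1 at 29.4 CPM in replicate 4, HES6 at 9.09 and GYG2 at 6.49 in replicate 1, LY6E at 14.2 and TBC1D13 at 16.3 in replicate 4, SLC1A4 at 9.05 in replicate 2, and SCN9A at 6.07, C3orf38 at 11.8 and MDK at 14.7 in replicate 3. Under BSA in control cells NME3 at 19.8, NOTCH3 at 16.1 and SRGAP3 at 8.90 stood apart in replicate 3, and UCHL3 at 23.5 in replicate 2. FLNC stood at 6.58 CPM in knockdown palmitate replicate 1. Among shares, long non-coding RNA was 1.065% in control palmitate replicate 1, miscellaneous RNA 0.790% in control BSA replicate 2, mitochondrial mRNA 0.209% in knockdown palmitate replicate 1 and snRNA 2.098% in knockdown palmitate replicate 2.

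Cytosolic ribosomal protein genes differed between the lines in their palmitate response by camera at the preset correlation (median interaction -0.069, 17 of 78 higher, adjusted p = 0.00923), and with an estimated correlation the adjusted p was 0.98.

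The genes called with knockdown were weighed against copy number and labelling. In 0 of 16 libraries were most of the 36 genes nearer to the other line's mean, though these genes were chosen by the line labels themselves. With genes chosen from a fit without the library in question (17 to 36 genes), 0 of 16 libraries again lay nearer to the other line for most genes (highest 38.9%), which argues against swapped line labels. For 0 of 36 genes did the 20 nearest tested protein-coding neighbours (median, called genes left out) move by at least 50% of the gene's change. This argues against a gain or loss that spans most of these neighbours as the whole cause. A shorter one, or one that holds other called genes, could be missed by this median. Over all 720 neighbours, however, the signed median was 0.0228 (bootstrap 0.0111 to 0.0348), above the 0.0171 that 95% of random draws stayed below, which was the limit set before the test, so a small regional part cannot be told apart from none. A change at a single gene or over a short stretch, and differences between lines that are not due to RNASET2, stay open. Knockdown as the biological explanation was not tested apart from line.

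The genes called with palmitate were weighed against a GC trend between libraries. Genes that rose had a median GC content of 43.4% and those that fell 58.4%, against 47.3% for all. With the correction 55.9% of the 750 genes called in the blocked fit kept their direction and call, 255 of 337 that rose and 164 of 413 that fell, a share between the limits set for either reading. Among those that lost the call the median absolute log2 change went from 0.23 to 0.17 while the SE went from 0.054 to 0.050, so calls ended because the change shrank. In control cells alone 42 of 222 (18.9%) were kept, which goes with a GC trend, and in knockdown cells 15 of 15 were. All 26 integrated stress response genes stayed higher after the correction, 20 past the threshold on average against 19 before it, so for these genes the trend is unlikely to be the whole cause. For the genes that fell and lost the call, GC content and palmitate cannot be told apart.

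The higher 18S and 28S rRNA share with palmitate could come from less complete removal of all rRNA. The 5.8S share changed by 0.098 ± 0.074 (log2, SE over 8 pairs) against 1.095 ± 0.158 for 18S and 28S. This argues against a loss of removal that touches every rRNA alike, though the SE takes the pairs as independent and may be too small. A change in the removal of the long rRNAs alone, in fragmentation or in the rRNA itself stays open.

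Other splits of the libraries were fitted to ask whether chance could be excluded. For palmitate in control cells 1 of 35 splits, the real one, gave 14 calls or more (highest other 0), for knockdown under BSA 1 of 35 gave 9 (highest other 0), and for knockdown under palmitate 1 of 35 gave 5 (highest other 1). For palmitate averaged over both lines 1 of 100 splits gave 281 (highest other 53), and for knockdown averaged over both treatments 1 of 100 gave 36 (highest other 8). If same-numbered libraries are paired, which is uncertain for control BSA replicates 1 and 2, only splits that part as many pairs are a fair reference. For a single contrast these were 8 of 35, the real one included, too few for a share under 0.05, with a highest other count of 0. For the averages 100 of the 128 such splits were drawn apart: 1 of 100 gave 281 calls with palmitate (highest other 12) and 1 of 100 gave 36 with knockdown (highest other 1). These splits exchange the pairs of a replicate number apart from each other, though same-numbered libraries of all 4 groups share deviations; exchanged together they leave 8 splits, too few for a share under 0.05. For palmitate in knockdown cells 35 of 35 splits gave as many as the real 0 calls, which any split must, so this decides nothing. The highest, 2, was in the split that follows batch, and with the block the real count was 15. For the interaction 100 of 100 gave as many as 0, which was fixed in the same way. The highest gave 1081, which points to a structure of the samples. The other splits with over 12 calls part fewer of the pairs, except 1 of the 100 drawn apart, which gave 36 for the interaction. It exchanges the lines under a single treatment, which turns the interaction into the averaged knockdown contrast, so its 36 calls are no reference.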

How the results depend on the processing

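Across 179 results of single genes, chosen by the size of their change past the threshold or by the smallest p in their list, which favours a stable direction, 3331 of 4100 values under an alternative kept direction and side of the threshold, 573 kept direction but not the threshold, 196 newly passed it, and none turned. Counts follow in the order palmitate in control cells, palmitate in knockdown cells, knockdown under BSA, knockdown under palmitate, interaction, palmitate averaged over lines and knockdown averaged over treatments; those not given were within 1.5 times the main count. The averages and the GC correction were chosen after seeing the data.

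DESeq2 gave 97, 24 and 20 for the first 3 and 60 for averaged knockdown. RLE size factors gave 0 for palmitate in control cells, 3 for knockdown under BSA and 1 under palmitate. TMM on protein-coding genes gave 1 for palmitate in knockdown cells and 3 for knockdown under palmitate. Protein-coding genes alone, with fewer features tested, gave 60 and 9 for palmitate in control and knockdown cells and 58 for averaged knockdown. No filter on low counts gave 103, 93, 38, 13 and 4 for the first 5 and 93 for averaged knockdown. A mean of at least 5 CPM gave 149 and 10 for the first 2 and 583 and 59 for the averages. No batch term gave 0 for palmitate in control cells, 3 and 0 for knockdown under BSA and palmitate, and 85 and 14 for the averages. The replicate block gave 222, 15 and 20 for the first 3 and 750 and 105 for the averages. With a GC correction it gave 51, 19, 21 and 12 for the first 4 and 516 and 118 for the averages. Batch 1 alone gave 0 for every contrast. Batch 2 alone gave 2, 3, 0 and 0 for the first 4 and 28 and 0 for the averages, with fewer samples. The groups compared alone gave 0 for palmitate in control cells, 2 for knockdown under BSA and 1 under palmitate. Except for fewer features or samples, the cause was not tested.

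With 1 library left out, counts ran from 0 to 41, 0 to 14, 3 to 6, 1 to 4, 100 to 273 and 17 to 36 for the contrasts other than the interaction, which stayed at 0. The lower RNASET2 in knockdown cells, averaged, passed the threshold with protein-coding genes alone (-0.33), at least 5 CPM (-0.35), the block (-0.34) and the block with a GC correction (-0.35). The correlation of palmitate responses turned to -0.0076 without a filter, -0.316 in batch 2 alone and -0.0893 without control BSA replicate 1, in a range of -0.0893 to 0.369 over libraries left out; the cause was not tested. Genes lower with palmitate and higher with knockdown numbered 2 without a filter. Lists past the threshold numbered 1, 1, 0, 0, 0, 2 and 0 with an estimated correlation. Depth over mRNA, 18.2% to 44.7% of a library, limits what low genes can show.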

Other observations

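The values in this part were picked after they were seen. AL158835.3 (ENSG00000280561, chromosome 10, 125707416 to 125749525, minus strand), an antisense RNA that overlaps EDRF1, had 12 to 48 counts in each of the 8 control libraries and 0 to 2 in each of the 8 knockdown libraries, with an average log2 fold change of -4.62 ± 0.37 (SE, edgeR adjusted p = 1.41e-05). EDRF1, on the other strand, stood at 0.08 ± 0.05 and EDRF1-AS1, which also overlaps it, at -1.07 ± 0.34 (edgeR adjusted p = 0.40). Within 500000 bases no other tested gene was called. Its 20 nearest tested protein-coding neighbours had a median of 0.00428, signed by its direction. This argues against a loss that spans most of them, while a change at this gene or over a shorter stretch stays open. Counts this low leave the size of the fold uncertain. Of the 36 features called with knockdown on average, 3 changed 2-fold or more: AL158835.3, AC009269.3 (-3.45) and AC092590.1 (-1.91).

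Several small or repeated features rose with palmitate beside 18S rRNA (1.16) and 28S rRNA (1.37), on the log2 scale averaged over both lines: MIR3178 (2.58), MIR3196 (2.42), MIR3960 (2.01), MIR4488 (1.97), MIR7704 (1.88), MIR7641-1 (1.14), FP236383.1 (1.16) and FP671120.1 (1.19). Their reads may be shared with near-identical copies. On the same scale 5.8S rRNA rose less, by 0.28, and was not called, and its share of counts changed by 0.098. Whether these features come from rRNA was not tested.

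MAP1LC3B rose by 0.62 with palmitate averaged over both lines and was the only 1 of 14 autophagy genes called, over all genes or adjusted over the list alone; 5 of 14 were higher, with a median of -0.02 (camera adjusted p = 0.365; adjusted p = 0.543 with an estimated correlation). The metallothionein MT1X rose by 1.00, and MT2A, the other 1 tested, stood at 0.42. Of the hypoxia and glycolysis genes 3 of 16 were higher, VEGFA rose by 0.29 and NDRG1 fell by 0.31 (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.119; adjusted p = 0.387 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, was lower with knockdown (-0.31, edgeR adjusted p = 0.0366), while 16 of 20 DNA replication genes were higher (camera adjusted p = 0.0781; adjusted p = 0.932 with an estimated correlation).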
